A study of Mus musculus with 6 samples.

How the data were processed

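The data were a table of read counts per gene for 6 mouse liver libraries, 3 labelled wild type and 3 labelled Atp7b knockout, all from animals kept on a high-fat diet for 24 weeks. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads, fragmented and copied, and dUTP was placed in the second strand before its removal, which keeps strand information in the library. The deposited values were raw whole-number counts, with 1 column per library and no pooling, as checked on the table. The submitters' processing notes name the genome build GRCm39 and the tool edgeR, without roles or versions. The aligner, the counting program, the annotation release and the use of strand in counting were not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical paralogs, could have been split or lost by the counting. Coordinates are those of the deposited table.

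Column names matched the sample titles, which also gave group and replicate number. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. No sequencing batch or date was given in the sources used here. Within a group, each pair of libraries differed by more than counting noise (chi-square per gene of at least 63.0), so no 2 held repeated counts of 1 library and each library was counted once. This does not tell whether they came from separate animals.

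The table held 30029 genes, of which 2283 had no count in any library and 94 repeated the symbol of another row. Total counts per library ran from 57886524 to 70965999, and 3 counts, the smallest level taken as detectable, corresponded to 0.034 to 0.058 CPM (counts scaled to library size). Such floors and all intervals cover counting error and the spread between samples as modelled, and amplified reads without molecular identifiers are not independent molecules.

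Genes were kept by edgeR's filterByExpr, which left 17606, and library sizes were scaled by the trimmed mean of M-values (TMM). Groups were compared with edgeR's quasi-likelihood F test with robust estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05, without a fold threshold. A log2 fold change is the labelled knockout over the labelled wild type, and its standard error (SE) was taken from the F statistic. Levels are TMM-scaled CPM as mean ± SD over 3 libraries.

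Before the data were examined, 30 lists of pathway or state genes and 13 lists of cell type markers were fixed, together with the test, the alternatives and the rule for the genes named. Lists with at least 5 tested members were compared with all other genes by limma's camera with an inter-gene correlation preset at 0.01, adjusted over the lists of the same kind. The same test with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run as alternatives. For each list the number of called members is given over all genes tested and adjusted over the list alone. The named genes were Atp7b, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, every library of one group beyond every library of the other and a symbol that is no clone name or receptor segment, and from each list up to 4 called members with the smallest p, or up to 2 members where none was called. Genes named beyond that rule were chosen after their values were seen, and this is said beside them.

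Genes within 10 Mb of Atp7b were compared with all other tested genes by Fisher's exact test, two-sided. Alternatives were DESeq2 size factors, total counts, total counts without the 20 most abundant genes, no filter, a filter of 10 counts in 3 libraries, DESeq2 1.42.0, limma voom, a threshold of 2-fold, the replicate number as a block, each library left out, and windows of 5 and 20 Mb. For DESeq2 the lists were tested on its Wald statistic with the same preset correlation. A correction for GC content and length, from the longest transcript of GENCODE vM21 matched by gene identifier for 97.1% of the tested genes, was chosen after seeing the data. So was a hypergeometric test, upper tail, of the called genes on the GO, KEGG and Reactome terms in the deposited annotation, with terms of 10 to 500 tested genes and all annotated tested genes as the background.

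The gene and list tests were run on simulated data of this comparison, with the means, spreads and library sizes of the real libraries, 17071 genes kept by the filter and 200 genes changed by known folds. Of 50 genes at each size, 5 were recovered at 1.5-fold, 26 at 2-fold, 42 at 4-fold and 47 at 8-fold. The changed genes were drawn from those with an average of about 1 CPM or more, so recovery of genes with fewer counts was not measured. Of 142 calls, 14 (9.9%) were unchanged genes, above the 5% the threshold aims at. A list of 25 genes raised by 2-fold was called by all 3 list tests, and none of 30 unchanged lists was called by any of the 3, with genes simulated as independent. Expression was not compared with protein, copper or histology, which were not analysed here.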

Results

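Polyadenylated RNA of mouse liver was sequenced to compare animals labelled Atp7b knockout with animals labelled wild type after 24 weeks on a high-fat diet. Atp7b is the copper-transporting ATPase of hepatocytes that is lost in Wilson disease. There were 3 libraries labelled wild type and 3 labelled knockout, with total counts of 57886524, 60166310 and 67280139 in the former and 68117601, 70965999 and 70720525 in the latter. Mitochondrially coded transcripts took 5.07% to 6.37% of the counts. On a principal component analysis of log2 CPM, the leading component held 45.7% of the variance and separated the groups, with labelled knockout replicate 3 the farthest out. The next component held 17.5% and set labelled wild-type replicate 1 apart from the rest.

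The targeted gene was not lower in the libraries labelled knockout. Atp7b (ENSMUSG00000006567; GRCm39 chromosome 8, 22482801 to 22550321) had 909, 1192 and 2051 counts in the libraries labelled wild type and 1987, 1908 and 2087 in those labelled knockout. Its level was 24.6 ± 8.42 CPM against 25.5 ± 1.77 CPM (SD, n = 3 each), a log2 fold change of 0.05 with a 95% interval of -0.47 to 0.57 (edgeR's quasi-likelihood test, adjusted p = 0.939). The gene total therefore did not check the labels, and the labels do not describe the allele or which exons it alters. All directions below compare libraries by their labels. Mt1 and Mt2, metallothioneins induced by copper and zinc and chosen here after their values were seen, had log2 fold changes of -0.86 ± 0.44 and -0.99 ± 0.30 (SE), neither past the test (adjusted p = 0.332 and 0.119).

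**Figure D1:**
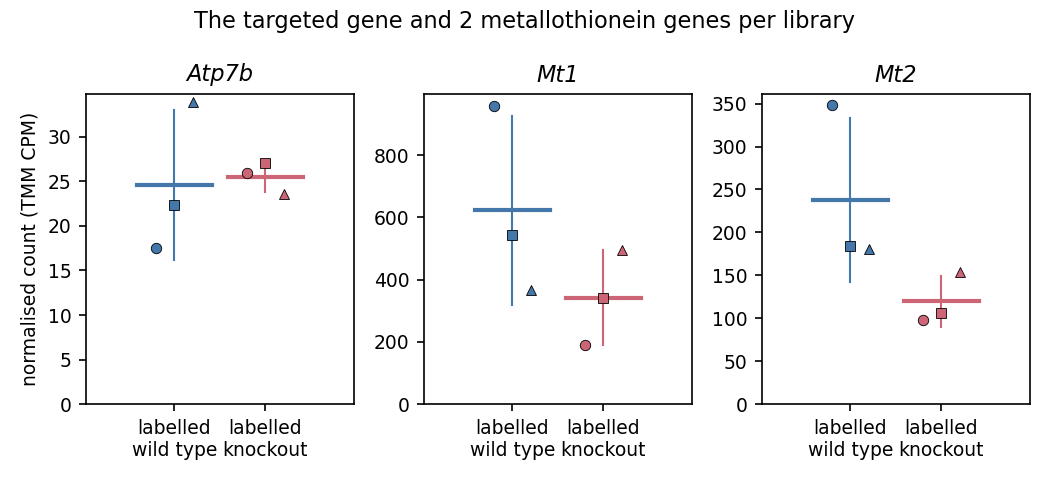
Normalised counts (TMM CPM, linear axis from 0) of Atp7b, Mt1 and Mt2 in each library, by label; bars are means and vertical lines SD over 3 libraries, circles, squares and triangles are replicates 1, 2 and 3. Atp7b averaged 24.6 CPM in the libraries labelled wild type and 25.5 CPM in those labelled knockout.

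Of the genes called lower in the livers labelled knockout, 9 were on the list of plasma acute-phase proteins. Those called higher included 5 members of the matrix list, 6 of the stellate cell list, 2 of the recruited macrophage list, 4 of the inflammation list and 1 of the cell cycle list. As groups these 6 lists did not pass with an estimated correlation (adjusted p = 0.137 to 0.412 with an estimated correlation). In that order the 6 lists held 8, 30, 10, 7, 6 and 6 such genes without labelled knockout replicate 2. They held 5, 6, 4, 9, 6 and 2 without wild-type replicate 1 and 1, 0, 1, 0, 1 and 0 without knockout replicate 3. Without knockout replicate 1 there were 3 in the acute-phase list and 0 in the other 5, and without wild-type replicate 2 or 3 there were 0 in all 6. Acute-phase Saa3 fell 16.6-fold and Orm1, an acid glycoprotein, fell 5.01-fold. Decorin (Dcn), a matrix proteoglycan, rose 2.45-fold and the macrophage gene Cd68 rose 2.92-fold. Of 17606 tested genes 253 were called, 164 higher and 89 lower in the libraries labelled knockout, and 204 of the 253 differed by at least 2-fold.

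These calls stood at the edge of the threshold, since 222 of the 253 had an adjusted p between 0.04 and 0.05 and the smallest was 0.0146, with 3477 genes at an unadjusted p under 0.05 and 25.7% of genes with groups that did not overlap, where chance gives 10%. Without labelled wild-type replicate 2 edgeR called 0 genes (2424 at an unadjusted p under 0.05), without wild-type replicate 3 it called 4, without knockout replicate 1 it called 11 and without knockout replicate 3 it called 33, while 382 were called without wild-type replicate 1 and 912 without knockout replicate 2; DESeq2 called 1867, which held all 253, and limma voom 69. Scaling by total counts moved the median of all genes from -0.02 to 0.31 on the log2 scale and gave 1008 calls, 93.4% of them higher, against 64.8% higher with TMM. Signs of list medians that turned under total counts, given below, turned with this shift of all genes: less the median of all genes, the bile acid, complex I and cholesterol synthesis medians were -0.26, -0.18 and -0.28 with TMM and -0.29, -0.18 and -0.29 with total counts. Of 43 lists, 27 held a called gene without labelled wild-type replicate 1, 0 without wild-type replicate 2, 2 without wild-type replicate 3, 3 without knockout replicate 1, 30 without knockout replicate 2 and 9 without knockout replicate 3. Fold changes are given on the TMM scaling.

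The acute-phase list, hepatocyte proteins that enter plasma in inflammation, had 9 of 25 members lower, 0 higher and 16 not called, and 22 lower when adjusted over the list alone. All 25 had a negative log2 fold change, with a median of -1.48 (-1.16 with total counts). Itih3, an inter-alpha-trypsin inhibitor chain, had 2896 ± 119 CPM in the libraries labelled wild type and 785 ± 205 CPM in those labelled knockout (log2 fold change -1.88 ± 0.24, adjusted p = 0.039). Saa3 (-4.05 ± 0.46, adjusted p = 0.039), Apcs (-2.58 ± 0.35, adjusted p = 0.0412) and Orm1 (-2.33 ± 0.34, adjusted p = 0.0416) fell as well. The fibrinogen chain Fgb went from 6801 ± 1341 to 2602 ± 514 CPM. Saa1 and Saa2, the most abundant serum amyloid genes, chosen after their values were seen, were 17.0-fold and 27.2-fold lower but did not pass the test (adjusted p = 0.0724 and 0.0785). Without labelled knockout replicate 1 they were 52.8-fold and 109-fold lower (adjusted p = 0.0137 and 0.00832). Saa1, Saa2 and Saa3, and Orm1 and Orm2, belong to families whose reads counting could have split. The list was lower as a group with the preset correlation (camera adjusted p = 5.19e-34), and adjusted p = 0.266 with an estimated correlation. The hepatocyte marker list had 2 of 18 members lower, Fgb and Ambp, and 16 not called, with 2 lower when adjusted over the list alone and a median of -0.33, which became 0 under total-count scaling. It was lower as a group (adjusted p = 7.92e-04, and 0.538 with an estimated correlation). Alb, the most abundant hepatocyte secretory transcript and chosen after its value was seen, had a log2 fold change of 0.37 ± 0.25 (adjusted p = 0.463).

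**Figure D2:**
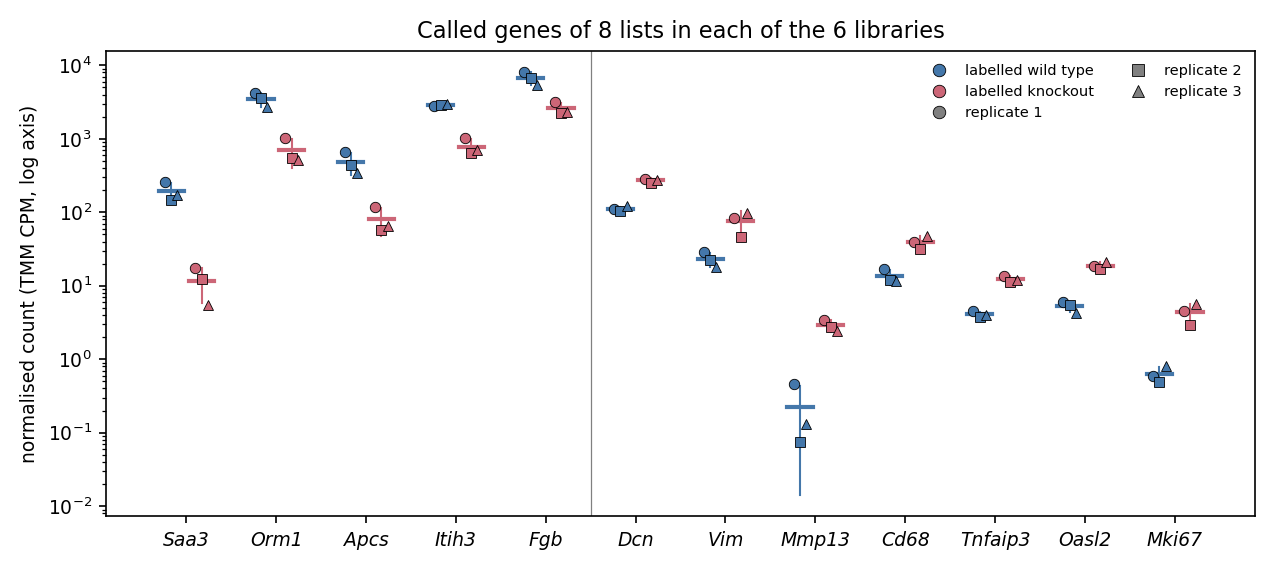
Normalised counts (TMM CPM, log axis) of 12 called genes in each library, with bars for the mean and vertical lines for the SD over 3 libraries per label; the grey line parts the genes that fell (left) from those that rose (right). For every gene drawn, the 3 libraries labelled knockout lie beyond the 3 labelled wild type; Dcn stood at 111 against 272 CPM and Itih3 at 2896 against 785 CPM.

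Matrix and mesenchymal lists held called genes on the higher side. Of 38 matrix and fibrosis genes, 5 were called higher and 0 lower, 33 were not called, and 32 were higher with 1 lower when adjusted over the list alone. The 4 with the smallest p were the collagenase Mmp13 (12.9-fold, adjusted p = 0.0458), the intermediate filament Vim (3.29-fold, 0.0464), the matrix glycoprotein Sparc (2.98-fold, 0.0477) and the cytokine Tgfb1 (1.98-fold, 0.0489). Without labelled wild-type replicate 1 Mmp13 was at 27.0-fold. The list median was 1.94, with a camera adjusted p of 1.26e-25, and adjusted p = 0.266 with an estimated correlation. Among 18 markers of stellate cells and fibroblasts, 6 were higher, 0 lower and 12 not called, and 12 were higher when adjusted over the list alone. Dcn rose from 111 ± 8.90 to 272 ± 18.5 CPM (log2 fold change 1.29 ± 0.14, adjusted p = 0.038). Col14a1, a fibril-associated collagen, rose 2.26-fold (adjusted p = 0.0412), Colec11, a collectin, rose 1.91-fold (0.0447) and Nes, nestin, rose 4.36-fold (0.0453). The stellate list was higher as a group (adjusted p = 6.48e-14), with adjusted p = 0.137 with an estimated correlation, the smallest of the lists, and its directional fry adjusted p was 0.0254.

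Recruited macrophage markers had 2 of 20 members higher, 0 lower and 18 not called, and 18 higher when adjusted over the list alone; Cd68, a lysosomal glycoprotein, rose 2.92-fold (adjusted p = 0.039) and cathepsin K (Ctsk) 10.5-fold (0.0473). The median was 1.71 (camera adjusted p = 4.11e-15, and adjusted p = 0.412 with an estimated correlation). Resident Kupffer cell markers had 0 of 16 members called and 1 higher adjusted over the list alone; the median was -0.04 (0.26 without labelled wild-type replicate 1, 0.04 without knockout replicate 3 and -0.17 to -0.13 without each of the others) and the mean -0.22 while camera gave the upward direction (adjusted p = 0.956), and Adgre1 (log2 fold change 0.92, adjusted p = 0.051) stood closest to the threshold. Kupffer markers held 2 genes called higher without labelled wild-type replicate 1 and 1 without knockout replicate 2. Bile duct markers had 2 of 15 members higher, Krt23 (15.9-fold, adjusted p = 0.038) and Anxa3 (2.83-fold, adjusted p = 0.0464), 0 lower and 13 not called, with 8 higher adjusted over the list alone and a median of 2.52 (camera adjusted p = 4.93e-07, and 0.54 with an estimated correlation). Without labelled knockout replicate 3 the bile duct median was 1.15, and without knockout replicate 2 the list held 9 called genes. Endothelial markers had 0 of 17 called, 1 higher adjusted over the list alone and a median of 0.37 (camera adjusted p = 0.0168, and 0.617 with an estimated correlation), with Vwf, von Willebrand factor, at 1.38 ± 0.32 (adjusted p = 0.0676). The endothelial list was not past its test without labelled wild-type replicate 2, knockout replicate 1 or knockout replicate 2 (adjusted p = 0.214, 0.303 and 0.0896). Its median was 0.60 without knockout replicate 3, and 1 member was called higher without knockout replicate 2.

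**Figure D3:**
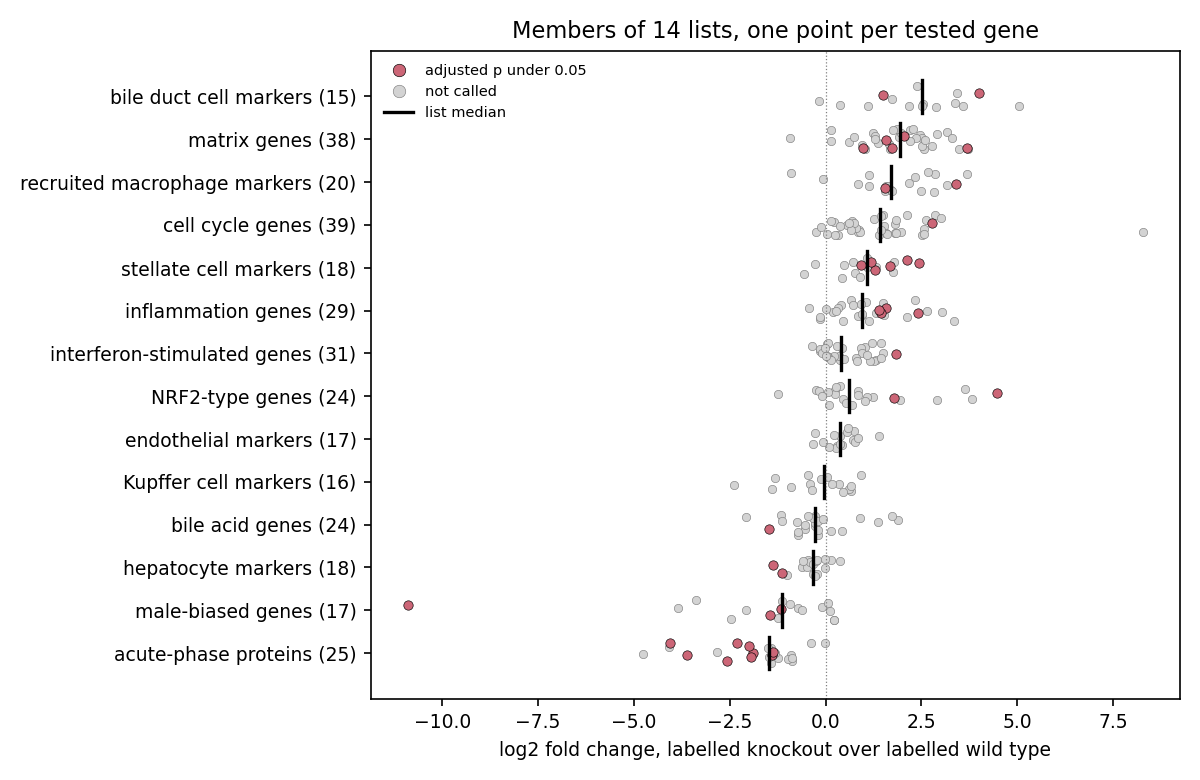
log2 fold change, labelled knockout over labelled wild type, of each tested member of 14 lists (number tested in brackets); filled red points passed the test at an adjusted p under 0.05, grey points did not, and the black bar is the list median. The acute-phase median lay at -1.48, the matrix median at 1.94 and the Kupffer cell median at -0.04; the Kupffer and bile acid medians turned positive under total-count scaling.

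The inflammation, interferon, cell cycle, p53 and immediate-early lists each held at least 1 gene called higher and 0 called lower. Of 29 cytokine, chemokine and NF-kB target genes, 4 were higher, 0 lower and 25 not called, and 11 were higher adjusted over the list alone. The NF-kB inhibitor Tnfaip3 rose from 4.07 ± 0.378 to 12.2 ± 1.28 CPM (log2 fold change 1.58 ± 0.17, adjusted p = 0.038), Vcam1, an endothelial adhesion molecule, rose 2.70-fold (0.0453) and the NF-kB subunit Relb 5.35-fold (0.0453). Interferon-stimulated genes had 1 of 31 higher, Oasl2 at 3.59-fold (adjusted p = 0.038), and 30 not called, with 11 higher adjusted over the list alone. In the cell cycle list 1 of 39 members was higher, the proliferation marker Mki67 at 6.86-fold (adjusted p = 0.039), 0 were lower, 38 were not called, and 14 were higher adjusted over the list alone. p53 targets had 1 of 22 higher, Phlda3 at 4.59-fold (adjusted p = 0.0464), and 8 adjusted over the list alone. Immediate-early genes, which also respond to the handling of tissue, had 1 of 16 higher, the transcription factor Klf6 at 3.56-fold (adjusted p = 0.0464), and 8 adjusted over the list alone. The medians of the inflammation, interferon, cell cycle, p53 and immediate-early lists were 0.96, 0.41, 1.43, 0.68 and 1.5, and camera gave adjusted p of 2.52e-10, 1.04e-06, 1.51e-12, 1.06e-05 and 4.12e-07. With an estimated correlation the adjusted p were 0.266, 0.307, 0.266, 0.287 and 0.307. Without labelled knockout replicate 3 the cell cycle median was 0.90. Without labelled wild-type replicate 1 the p53 median was 1.17 and the interferon median 0.84. The latter was 0.26 without wild-type replicate 3 and 0.25 without knockout replicate 2. Called higher without knockout replicate 2 were 3 interferon, 4 p53 and 3 immediate-early genes, and without wild-type replicate 1, 5 interferon genes. The unfolded protein list had 1 of 25 higher, the stress factor Atf3 at 8.20-fold (adjusted p = 0.0462), 24 not called and a median of -0.26 that turned positive under total-count scaling (camera adjusted p = 0.187). With 1 library left out that median ran from -0.43 without labelled knockout replicate 1 to -0.09 without wild-type replicate 1. The list passed without wild-type replicate 3 or knockout replicate 1 (adjusted p = 0.0194 and 0.00116). Atf3 was at 12.4-fold without labelled wild-type replicate 1.

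Of 17 genes known to be higher in male mouse liver, 3 were called lower, 0 higher and 14 not called, with 6 lower adjusted over the list alone. Of the 17, 13 had a negative and 4 a positive log2 fold change. The male-biased median was -1.14 (camera adjusted p = 1.6e-07, and 0.307 with an estimated correlation), and -0.59 without labelled knockout replicate 3. Moxd1, a member of the copper-dependent monooxygenase family, had 1121, 14757 and 13318 counts in the libraries labelled wild type and at most 15 in those labelled knockout, with 0 in replicate 2, which allows up to 0.043 CPM (log2 fold change -10.90 ± 1.47, adjusted p = 0.0453). Its log2 fold change was -12.11 without labelled knockout replicate 1 (adjusted p = 0.139). Cyp2u1, a cytochrome P450, and Nudt7, a peroxisomal coenzyme A hydrolase, fell 2.24-fold and 2.74-fold (adjusted p = 0.0462 and 0.0464). Of 19 female-biased genes 1 was called higher, 0 lower and 18 not called, with 9 higher adjusted over the list alone, 16 positive and 3 negative log2 fold changes, and a median of 2.38 (camera adjusted p = 3.57e-07, and 0.266 with an estimated correlation). Fmo2, a flavin monooxygenase, rose from 7.40 ± 1.20 to 35.4 ± 5.12 CPM, a log2 fold change of 2.26 ± 0.17 and the smallest adjusted p of all genes (0.0146). Of markers of sex, chosen after their values were seen, Y-coded Ddx3y had at least 2130 counts in each of the 6 libraries, and Xist at most 15.

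Enzymes of detoxification and sugar metabolism held called genes on the higher side. Among 24 antioxidant genes of the NRF2 kind, 2 were higher, 0 lower and 22 not called, and 11 were higher with 1 lower adjusted over the list alone; the glutathione transferases Gsta1 and Gsta4 rose 22.0-fold and 3.41-fold (adjusted p = 0.0416 and 0.039), and reads of these paralogs could be shared. The median was 0.60 (camera adjusted p = 4.86e-07, and 0.266 with an estimated correlation). Of 28 xenobiotic genes Cyp3a11, the main hepatic drug oxidase of its family, was higher (902 ± 368 to 4278 ± 1243 CPM, adjusted p = 0.0453), 27 were not called, and 3 were higher and 1 lower adjusted over the list alone (median 0.16, camera adjusted p = 0.196). The xenobiotic list passed without labelled knockout replicate 1 or 3 (adjusted p = 0.0478 and 0.00229). With 1 library left out its median ran from -0.04 without knockout replicate 2 to 0.27 without knockout replicate 3. In the glucose list 3 of 25 were higher and 22 not called, with 7 higher adjusted over the list alone: Igfbp1, an insulin-repressed binding protein, by 3.56-fold, and the glycolytic enzymes Pkm and Hk2 by 2.69-fold and 3.34-fold (adjusted p = 0.0416, 0.0453 and 0.0464). That list had a median of 0.13 (camera adjusted p = 0.0117, and 0.287 with an estimated correlation). Without labelled wild-type replicate 1 its median was -0.03 and it was not past its test (adjusted p = 0.143). Bile acid genes had 1 of 24 lower, Cyp2c70, which makes muricholic acids, from 686 ± 132 to 245 ± 37.5 CPM (adjusted p = 0.0416), 23 not called, and 4 lower with 1 higher adjusted over the list alone. The bile acid median of -0.28 became 0.02 with total counts (camera adjusted p = 0.00749, and 0.448 with an estimated correlation). It was -0.50 without labelled knockout replicate 2 and -0.18 without knockout replicate 3.

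Lipid lists held no called gene with all 6 libraries. Without labelled wild-type replicate 1 the droplet, oxidation, lipoprotein and receptor target lists below held 4, 5, 3 and 3 genes called higher, and 2 cholesterol synthesis, 2 fatty acid synthesis, 1 lipoprotein and 1 receptor target gene were called lower. Without knockout replicate 2 there were 2 receptor target genes higher, and 1 cholesterol synthesis and 1 lipoprotein gene lower. Lipid droplet genes (20 tested) had a median of 0.51 (camera adjusted p = 0.00144, and 0.634 with an estimated correlation). Adjusted over the list alone, 2 droplet genes were higher and 1 lower. Bscl2 was at -0.61 ± 0.13 (adjusted p = 0.0579) and Hsd17b13, a droplet enzyme, at 0.86 ± 0.20 (adjusted p = 0.0694). Without labelled knockout replicate 2 the droplet list was not past its test (adjusted p = 0.127). Fatty acid oxidation genes (27 tested) had a median of 0.31 (camera adjusted p = 0.0195, and 0.764 with an estimated correlation) and 0 members past the test adjusted over the list alone. The oxidation list was not past its test without labelled wild-type replicate 2, wild-type replicate 3 or knockout replicate 2 (medians 0.17, 0.25 and 0.14, adjusted p = 0.151, 0.111 and 0.729). Cholesterol synthesis genes (25 tested) had a median of -0.30, which was 0.02 under total counts, and 0 adjusted over the list alone (camera adjusted p = 0.0159, and 0.746 with an estimated correlation). Its median was -0.52 without labelled wild-type replicate 1. It was not past its test without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1 (adjusted p = 0.151, 0.108 and 0.1). Liver X receptor targets (13 tested) had a median of 0.55, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.024, and 0.266 with an estimated correlation); Pltp, phospholipid transfer protein, was at 1.05 ± 0.22 (adjusted p = 0.0561). The receptor target list was not past its test without labelled wild-type replicate 1 or 2 (adjusted p = 0.0526 and 0.0507). Fatty acid synthesis (23 tested, median -0.26) and lipoprotein genes (22 tested, median -0.21 with a mean of 0.06) were not past the list test (adjusted p = 0.23 and 0.486), and both medians turned positive under total counts; 0 synthesis genes and 2 higher and 2 lower lipoprotein genes passed adjusted over the list alone. The synthesis list passed without labelled wild-type replicate 1 (median -0.40, adjusted p = 4.14e-05), and its median was -0.07 without wild-type replicate 2, -0.05 without wild-type replicate 3 and -0.17 without knockout replicate 3. The lipoprotein median ran from -0.34 without labelled knockout replicate 2 to -0.08 without knockout replicate 3.

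Of the metal lists, copper handling had 1 of 20 members higher, App, the amyloid precursor protein that binds copper, at 3.13-fold (adjusted p = 0.0447), and 19 not called, with 1 higher adjusted over the list alone; its median was -0.08 (0.04 without labelled wild-type replicate 1) and its mean 0.02 (camera adjusted p = 0.793). Metal response genes had 0 of 17 called and a median of 0.23, or -0.15 without labelled knockout replicate 1 and 0.40 without knockout replicate 3 (camera adjusted p = 0.793). Adjusted over the list alone, 2 metal response genes were higher and 2 lower. The manganese and zinc transporter Slc30a10 was at -1.60 ± 0.33 (adjusted p = 0.0551) and Slc39a10 at 1.05 ± 0.28 (adjusted p = 0.0894). Iron handling had 1 of 20 higher, the transferrin receptor Tfrc at 1.89-fold (adjusted p = 0.0447), 19 not called, 2 higher and 2 lower adjusted over the list alone, and a median of -0.13 (camera adjusted p = 0.367). With 1 library left out the iron median ran from -0.25 without labelled wild-type replicate 2 to -0.01 without wild-type replicate 1. Nuclear-coded subunits of complex I had 0 of 35 called and a median of -0.20 (camera adjusted p = 7.85e-04, and 0.69 with an estimated correlation); cytochrome c oxidase genes and mitochondrially coded messages had medians of -0.10 and -0.20 and were not past the list test (adjusted p = 0.0989 and 0.124), with 0 called in all 3 lists when adjusted over the list alone. Complex I was not past its test without labelled knockout replicate 1 (median -0.09, adjusted p = 0.0819). Cytochrome c oxidase passed without labelled wild-type replicate 3 or knockout replicate 2 (adjusted p = 0.0402 and 0.0192) and the mitochondrially coded list without knockout replicate 2 (0.0133). Their medians ran from -0.18 without labelled knockout replicate 2 to -0.02 without knockout replicate 1, and from -0.32 without knockout replicate 2 to -0.01 without knockout replicate 3. The copper, iron and all 3 respiratory medians turned positive under total counts. Pericentral genes had 0 of 19 called, 2 lower adjusted over the list alone and a median of -0.36 (camera adjusted p = 2.28e-04, and 0.448 with an estimated correlation), with the WNT inhibitor Notum at -0.85 ± 0.18 (adjusted p = 0.0563). The pericentral list held 1 gene called lower without labelled wild-type replicate 1 or knockout replicate 2, and its median was -0.58 without labelled knockout replicate 2 and -0.20 without knockout replicate 3. Periportal and clock genes, with 16 and 17 tested, were not past the list test (adjusted p = 0.475 and 0.434). The periportal list passed without labelled knockout replicate 3 (adjusted p = 0.0288). Genes of fetal liver and tumours had 2 of 18 higher, Anxa5, a phospholipid-binding annexin, at 3.28-fold (adjusted p = 0.039) and S100a11, a calcium-binding protein, at 4.28-fold (0.0498), with 10 higher and 1 lower adjusted over the list alone (median 1.38, camera adjusted p = 2.03e-05, and 0.357 with an estimated correlation). That list held 7 genes called higher without labelled knockout replicate 2, 3 without wild-type replicate 1 and 1 without knockout replicate 3. It held 0 without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1.

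Among other cell types, T and natural killer cell markers had 0 of 22 called, 1 higher and 1 lower adjusted over the list alone, and a median of 0.78 (camera adjusted p = 0.00863, and 0.594 with an estimated correlation). Without labelled knockout replicate 3 that median was 0.26 and the list was not past its test (adjusted p = 0.121), while 1 member was called higher without knockout replicate 2. Il7r was at a log2 fold change of 2.87 ± 0.61 and Cd4 at -1.87 ± 0.41, neither called (adjusted p = 0.0566 and 0.0596). B cell (15 tested), neutrophil (13), erythroid (10), fat tissue (8) and mesothelium or muscle markers (9) held no called gene with all 6 libraries and were not past the list test, with adjusted p of 0.463, 0.373, 0.956, 0.284 and 0.956. The B cell list, with a median of -0.18 without labelled knockout replicate 3, passed without wild-type replicate 3 (median 0.92, adjusted p = 0.0253) and the fat tissue list without wild-type replicate 1 (median 1.26, adjusted p = 5.01e-07), with 3 genes called higher. Without knockout replicate 2, 1 B cell gene was called higher and 1 mesothelium or muscle gene lower. Of the acinar pancreas list 3 members were tested, too few for a list test, and 0 were called.

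The largest rises by the fixed rule were Gsta1, the inhibitory synapse gene Insyn1 (16.7-fold), Krt23, Mmp13, the cytochrome P450 Cyp1b1 (12.6-fold), the carboxypeptidase-like Cpxm1 (11.2-fold), Ctsk, the adaptor Lat2 (9.95-fold), the glycerol channel Aqp7 (8.94-fold) and Atf3. The largest falls were Moxd1, the myeloid protease Prtn3 (24.5-fold lower), Saa3, Orm2 (12.3-fold), the chitinase-like Chi3l1 (8.5-fold), the kinase Ptk6 (6.91-fold), the adhesion molecule Cadm4 (6.84-fold), Xirp1 (5.99-fold), Apcs (5.96-fold) and the anion transporter Slc22a7 (5.53-fold). Of these, Mmp13 and Atf3 were at 27.0-fold and 12.4-fold without labelled wild-type replicate 1, and Orm2 at 21.9-fold without knockout replicate 1. Without labelled knockout replicate 3, Gsta1, Krt23, Cpxm1, Saa3, Cadm4 and Slc22a7 still passed (adjusted p = 0.0335, 0.0408, 0.0432, 0.00721, 0.00721 and 0.0416). The other genes named here as largest rises or falls did not. Among those, Cyp1b1 and Lat2 were at 6.63-fold and 6.03-fold (adjusted p = 0.0555 and 0.0681). Prtn3 went from 28.4 ± 4.63 to 1.15 ± 0.762 CPM (adjusted p = 0.0416), while Elane, a neighbouring neutrophil elastase gene, was at 0.617 ± 0.242 and 0.131 ± 0.115 CPM and not called (adjusted p = 0.278).

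The test did not show genes near Atp7b to be called more often than the rest. Within 10 Mb on chromosome 8, 2 of 123 tested genes (1.63%) were called against 251 of 17482 elsewhere (1.44%), an odds ratio of 1.13 with a 95% interval of 0.135 to 4.23 (Fisher's exact test, two-sided, p = 0.697). The 2 genes, chosen after their values were seen, were Kbtbd11 (log2 fold change 2.53) and Atp11a (-1.75). Nek5, which starts at 22563632 on this chromosome and was also chosen after its values were seen, was not called (adjusted p = 0.106). It had 0, 6 and 0 counts in the libraries labelled wild type and 39, 28 and 101 in those labelled knockout (log2 fold change 4.15).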

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

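Of the alternatives given in this paragraph, only the correction for GC content and length was chosen after seeing the data. The count of 253 called genes depended on the test, the scaling and single libraries, and the cause was not tested. Calls numbered 1867 with DESeq2 (1313 higher, 554 lower), 69 with limma voom (30 higher, 39 lower, 68 of them among the 253), 473 with no filter (347 higher), 1008 with total counts (941 higher), 876 without the 20 most abundant genes in the total (806 higher) and 393 after the GC and length correction (152 lower); a 2-fold threshold left 58 lower genes. Leaving out each replicate in turn gave 0 to 912 calls, 0 to 730 higher and 0 to 182 lower, with 0 without labelled wild-type replicate 2 (2424 at an unadjusted p under 0.05 in edgeR), 4 without wild-type replicate 3 and 912 without knockout replicate 2. With the replicate number as a block 4 genes were called, 1 higher and 3 lower. Same-numbered libraries did not deviate together (correlations of 0, -0.02 and -0.05). Expression thus showed no pairing by number, which does not exclude that same-numbered libraries shared a litter or day. Of the genes called near Atp7b, 2 in the planned fit, there were 13 with DESeq2, 1 with size factors, 1 with limma voom, 4 with no filter, 7 with total counts, 8 without the 20 most abundant genes, 0 with the replicate block, 0 within 5 Mb (11 at an unadjusted p under 0.05 in edgeR), 4 within 20 Mb and 0 to 9 when a replicate was left out (9 without knockout replicate 2). The counts of 13, 7 and 9 came with 1867, 1008 and 912 calls over all genes. Outside the planned fit the share near Atp7b was not compared with that of other genes, so these counts show no excess there. With an estimated correlation 0 gene lists were higher and 0 lower, and 0 cell type lists were higher and 0 lower, where 3 gene lists and 1 cell type list had an unadjusted p under 0.05; fry gave 0 and 0 gene lists (12 at an unadjusted p under 0.05) and 1 and 0 cell type lists. Total counts, with or without the 20 most abundant genes, gave 2 lower cell type lists, hepatocyte and neutrophil. These were lower only relative to other genes: with total counts their medians were 0 and 0.09, against 0.31 for all genes. The Atp7b log2 fold change ran from -0.14 to 0.37 and stayed uncalled in all 16 alternatives. Of 96 named genes besides Atp7b, 21 passed the test with DESeq2 that had not before, and 31 lost it with limma voom, 50 with the block and 54 without wild-type replicate 2; none reversed a called direction in any alternative run. Of 42 lists tested with the preset correlation, leaving out 1 replicate ended the call of 1 to 4 and added a call for 0 to 3. Depth was 57886524 to 70965999 counts per library, with a common coefficient of biological variation of 0.32; genes with few counts, such as Mmp13 with 4 to 24 in the libraries labelled wild type, carry more counting error.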

Other observations

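The annotation terms were tested, by a test chosen after seeing the data, for genes that rose or fell. The test treats genes as independent, so its p-values can be too small. The matrix and acute-phase lists had estimated inter-gene correlations of 0.62 and 0.68. It used calls made with all 6 libraries, whereas edgeR called 0 genes without labelled wild-type replicate 2 and 4 without wild-type replicate 3. Of 3797 GO terms, 27 were enriched among the higher genes and 2 among the lower ones. Collagen-containing extracellular matrix held 21 higher genes of 239 tested (8.79%, against 1.10% of the 14494 annotated genes, adjusted p = 7.24e-10), among them Dcn, Lum, Fbn1, Lama2 and Tgfbi, which code for proteins of the matrix. The term for cellular response to interferon-beta held 6 of 56 (adjusted p = 0.00858) and monocyte differentiation 6 of 23 (adjusted p = 2.1e-04). The 6 genes of the former were interferon-inducible paralogs, Ifi203, Ifi204, Ifi207, Ifi209, Ifi213 and Mndal, and the latter held 5 of these and Csf1. Counting could have split reads among these paralogs, so neither term rests on independent genes, and the latter says little of monocytes. Among the lower genes, serine-type endopeptidase inhibitors held 7 of 71 (adjusted p = 5.87e-04), acute-phase response 5 of 30 (adjusted p = 0.00132) and the KEGG term for complement and coagulation cascades 5 of 86 (adjusted p = 0.0294), with C8b, Cpb2, Fgb, Fgg and Serpinf2. No Reactome term of 1619 passed in either direction.

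The tests below of a wrong label, swapped labels, the share of hepatocytes, library scaling and the sex-biased genes were chosen after their results, or values bearing on them, had been seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 253 called genes and the highest other split 2, with 1 of the 10 as large. For gene lists past the threshold with the preset correlation the real split gave 19 and the highest other 19, with 2 of the 10 as large, and for cell type lists 6 and 7, with 6 of the 10 as large. The number of list calls with a preset correlation was thus not particular to the labelled split. Every other split still sets 2 libraries of 1 label against 2 of the other, so part of any group difference stays in it. The counts therefore do not tell whether list calls arise without a group difference.

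Atp7b counts that were not lower in the libraries labelled knockout could have several explanations. An allele that lowers the transcript to 0.5 or less would make at least 2 libraries labelled knockout low with a single wrong label. With right labels it would make all 3 low. They had 26.0, 27.1 and 23.6 CPM, against 24.6 in wild type. These values argue against such an allele under either labelling, so they cannot tell a single wrong label from right labels. With such an allele, swapped labels would put the log2 fold change at 1 or above, and right labels would put it as far on the negative side. Its interval of -0.47 to 0.57 held neither, so it does not tell swapped labels from right ones. With an allele that leaves the transcript, Atp7b checks no label; knockout replicate 2 and wild-type replicate 1 correlated at 0.959 in log2 CPM, against 0.949 for the former with knockout replicate 3 and 0.959 for the latter with wild-type replicate 3, while by chi-square per gene all 6 libraries lay nearest their own group. Strain DNA around the targeted gene cannot be told apart from other causes, with an odds ratio of 1.13 for calls near Atp7b whose interval reaches 4.23, and an allele that stops the protein and keeps the messenger RNA was not tested, because the table holds gene totals and no exons.

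The acute-phase list held genes called lower and the matrix, macrophage and inflammation lists genes called higher. A smaller share of hepatocytes as the only cause is argued against for the acute-phase genes by the 17 hepatocyte markers outside that list. The median of those markers, -0.33 (SD 0.37), lay well above the acute-phase median of -1.48. Of the 17, 15 were lower and 2 higher, so a smaller share as part of the cause stays open. For the matrix and macrophage genes, endothelial markers do not decide it. Their median of 0.37 lay below the matrix and recruited macrophage medians by more than the larger SD (gaps 1.57 and 1.34, SD 1.02 and 1.13). This failed for the matrix median without labelled wild-type replicate 1 (gap 1.46, SD 1.89) and the macrophage median without knockout replicate 3 (gap 0.74, SD 1.10). A smaller share would raise Kupffer markers too, yet their median was -0.04 (SD 0.91), against 1.71 for recruited macrophage markers. The 2 medians were 0.04 and 1.34 without knockout replicate 3, and 0.26 and 2.17 without wild-type replicate 1. Kupffer markers thus did not rise as a set, but members went both ways (8 positive and 8 negative log2 fold changes). Their median therefore does not decide how far a smaller share raised the macrophage genes. For the macrophage and the matrix genes a smaller share stays open. Library scaling is argued against because the acute-phase median was at most -1.16 in 4 scalings, and a GC or length trend because the median was -1.47 after correction. Another candidate explanation that stays open is an acute-phase state in the libraries labelled wild type, or a genotype effect on hepatocyte cytokine signalling; no library without the diet was analysed here, so neither was tested.

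Of 17 male-biased genes 3 were called lower, and the summed major urinary protein (Mup) genes stood at 70547, 92499 and 99491 CPM in the libraries labelled wild type and 33266, 40700 and 8525 CPM in those labelled knockout, lowest in replicate 3. Female animals are argued against by Xist, at most 12 counts in the libraries labelled knockout, and by Y-coded genes at the level of the other libraries. A shift of reads between Mup paralogs is argued against by the sum, which was 4.34-fold lower in replicate 3 than in the mean of the other two. Without replicate 3 the list median was -0.59, nearer 0 than the -1.14 with it, and 0 members were called. Members went both ways (13 negative, 4 positive, SD 2.65), so the median does not decide whether the list changed in replicate 3 alone. The Mup sum was below each wild-type library in replicates 1 and 2 as well. No single Mup gene was called, and the smallest adjusted p in edgeR's test was 0.0859, for Mup2. Mup genes were not lower in every library labelled knockout: in replicate 2 Mup21 had 245 CPM, against a wild-type mean of 243. Mup20, at a log2 fold change of 0.11, did not follow the other Mup genes, and no biological explanation was tested.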
